A study of Mus musculus with 71 samples.

How the data were processed

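Serum miRNA of 71 mice was measured on 1-colour Agilent mouse miRNA arrays, with 1 array per mouse and 12 groups of 5 or 6 mice, and 10 ng of miRNA was labelled for each, per the labels. The deposited array files hold spot signals in intensity units, per the file headers after background subtraction and spatial detrending by Agilent's Feature Extraction, with no scaling between arrays. The authors also deposited a table of 350 miRNAs in log2 units, with column medians from 5.86 to 6.28, made with limma per the labels, and the method of normalization is not stated. Each column of that table correlated best with its own array for 71 of 71 arrays (Pearson r across miRNAs from 0.909 to 0.986), with a median slope of 0.763, so its log2 differences are smaller than those computed here. The comparisons below start from the array files.

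The processed signals of a probe's replicate spots were averaged without spots marked as outliers. A probe counted as detected on an array when more than a share of 0.5 of its spots were marked above background. Each array was divided by its 75th percentile over the 120 probes detected on all arrays and brought to a common level, and signals below a floor of 16.6 (4.05 in log2 units, the 5th percentile of detected signals) were set to the floor. The brightest probe stood for each miRNA. Where no array of a group was above background, its arrays were raised to their lowest detected signal and the change is given as at least a fold. Of 1247 miRNAs with 3105 probes, the 280 detected on at least 4 arrays of at least 1 group were tested. Detection over background on each array sets the precision, and the number of mice limits it. Positions of probes are those of the array design on mm9, where 180 of the tested miRNAs have at least 1 mapping, and were not aligned again because no genome was at hand.

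Group means were fitted on all 71 arrays with limma's lmFit and eBayes with a trend, without a block, and 17 contrasts were tested with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The haemolysis index and the number of detected miRNAs were compared between treated and control mice by exact two-sided permutation of the mice, adjusted over the 6 comparisons, and between weeks and models by permutation, with 1e+05 draws where groups were larger. In all, 17 miRNA lists written from general knowledge were used: red blood cell, platelet, myeloid cell, lymphocyte, inflammation induced, cartilage and osteoarthritis, liver, skeletal and cardiac muscle, endothelium, bone and fibroblast, brain and nerve, let-7 family, miR-17 to miR-92 clusters, miR-29 and miR-30 families, Dlk1-Dio3 cluster, Sfmbt2 intron cluster, and GC-rich or recently numbered. Of these, 16 with at least 3 tested members were tested with camera at a preset correlation of 0.01, in 240 tests adjusted together, and the Dlk1-Dio3 cluster, with miR-370-3p and miR-494-3p alone, was not. Lists share members, such as miR-16-5p in the red cell and cartilage lists. The Sfmbt2 intron cluster list was filled by name, with tested miRNAs of the miR-466, miR-467 and miR-669 series, and not by position. Except for what is named below as added, picked or shortened later, groups, lists, tests, thresholds, alternatives and the rule for naming miRNAs were chosen before the data were examined.

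The rule names, for each contrast, the 10 highest and 10 lowest fold changes among miRNAs past the threshold, or with fewer than 10 the smallest p until 10 are named, with up to 4 members of each list by smallest p, and miR-451a and miR-23a-3p always. After the results were seen and to keep the text short, comparisons without any call name fewer than 10, from the smallest p on, except AIA against saline at week 4. Some list members, miR-150-5p in AIA against DMM mice, miR-483-5p there, and miR-150-5p between weeks 4 and 16 were picked after their values were seen.

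On data simulated without any change, with 280 miRNAs in 20 simulations, the preset list tests gave an adjusted p under the threshold in 22.8% of 320 tests, and the tests with an estimated correlation in 0%. On simulated changes of 1 log2 unit, limma found 34.5% for 6 against 6 mice and 69.0% for 12 against 12, and of 2 log2 units 88.5% and 98.0%. It made a mean of 0.05 and 3 false calls per simulation, and a false call was made in 1 and 5 of 20 simulations.

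Alternatives covered 3 other scalings, normexp background correction with an offset of 50, the floor, the filter, the summary of probes, the authors' table, slide as a fixed or random block, the replicate number as a block, array position, array weights, a fit without a trend and a fit of the compared groups alone. Each mouse was left out in turn for the 8 contrasts between 2 single groups only, so the counts of calls between weeks had no such test. The covariate for array signal, the removal of 4 arrays with low signal, and the contrasts of all immunised with all operated mice at week 1 and of the weekly changes between models were added after seeing the data, as were the list means and index values without single mice. The haemolysis index as a covariate was added then too, but what it should show between weeks 1 and 4 was written down before that test was run. Week 1 against later weeks in DMM and sham mice was left out because no slide holds both. Calculations used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.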

Results

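Serum miRNAs were measured on 71 1-colour Agilent mouse miRNA arrays, 1 per male C57BL6 mouse, in 12 groups made of 4 treatments at 1, 4 and 16 weeks. Destabilisation of the medial meniscus (DMM) is a surgical model of osteoarthritis in which the ligament holding the medial meniscus to the tibia is severed. Its controls were sham operated. Antigen-induced arthritis (AIA) is an inflammatory model in which mice immunised with methylated bovine serum albumin in complete Freund's adjuvant receive the antigen into the knee. Its controls were immunised in the same way and received saline into the knee. Each group held 6 mice, except the week 16 DMM group with 5. DMM and sham mice are called operated below, and AIA and saline mice immunised. Of 1247 mouse miRNAs on the array, 72 were above background in all mice, 420 in at least 1, and 280 entered the tests. Group means of detected miRNAs per mouse lay between 204 and 270, and the 75th percentile of signal used for scaling had group means of 1255 to 3421 intensity units. The arrays lay on 9 slides. Of these, 6 slides each held 1 array of all 4 week 1 groups and of the AIA and saline groups of weeks 4 and 16. The other 3 slides held the DMM and sham arrays of weeks 4 and 16, so week 1 was not set against the later weeks in operated mice. Fold changes are log2 differences with limma's standard error (SE), and adjusted p is Benjamini-Hochberg adjusted over the 280 miRNAs of a comparison. miRNA lists were tested with camera at a preset correlation, and none of the 45 list calls held with an estimated correlation. The 45 calls came from 240 preset tests. On simulated data without any change 22.8% of such tests passed, adjusted over the lists of each fit and not over all 240. A list call below thus describes the members' shared direction and is not by itself evidence of a change.

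The first comparison asked which serum miRNAs differ between arthritic mice and immunised controls. No miRNA passed at week 1, 4 or 16. At week 4, the miRNAs nearest to the threshold were miR-324-3p (log2 fold change 0.66, SE 0.18), miR-5620-3p (-0.96, SE 0.27), miR-223-3p, an abundant miRNA of neutrophils and monocytes (1.11, SE 0.33), and miR-3098-5p (-1.07, SE 0.32), each at an adjusted p of 0.0913. miR-223-3p stood at 12.12 ± 0.19 (SD, n = 6) log2 units in AIA mice and at 11.01 ± 0.96 (SD, n = 6) in saline mice, and was higher in AIA on 5 of 6 slides. miR-324-3p was above background in 6 of 6 AIA and 1 of 6 saline mice, and miR-5620-3p in 2 and 4 of 6. With normexp miR-324-3p stood at -0.28. miR-22-3p (1.01), miR-350-3p (1.25), miR-425-5p (0.80), miR-1934-3p (-0.83), miR-128-3p (1.41) and miR-326-3p (1.13) followed, at an adjusted p of 0.13. limma gave 0 calls at each week, with 5, 41 and 1 miRNAs at an unadjusted p under 0.05 at weeks 1, 4 and 16, where 14 are expected by chance. With slide as a block, 2 miRNAs passed at week 4, miR-324-3p and miR-5620-3p, and with array weights, whose estimation did not converge, 68, 1 and 1 passed at the 3 weeks. Without week 4 saline replicate 6, 10 passed, miR-223-3p among them. Without saline replicate 4, 2 passed (miR-3098-5p and miR-324-3p), and without saline replicate 3, 1 (miR-22-3p). Without saline replicate 5, the array with the lowest signal of all, none passed and the smallest adjusted p in limma rose to 0.67. At week 1 the smallest p belonged to miR-669f-3p (1.15, SE 0.35, adjusted p = 0.513), which passed without saline replicate 1 (adjusted p = 0.0343). Next came miR-150-5p, a miRNA of mature lymphocytes (-0.83, SE 0.35, adjusted p = 1), and miR-483-5p (0.63, SE 0.29). At week 16 the smallest p belonged to miR-429-3p (0.45, SE 0.22, adjusted p = 0.997). For 6 against 6 mice the median 95% confidence interval reached 0.79 log2 units (1.72-fold) to each side. The red cell miRNA miR-451a had fold changes of 0.09, 0.83 and -0.16 at weeks 1, 4 and 16, and miR-23a-3p, its usual reference in serum, of 0.20, 0.74 and 0.28. Both week 4 values leaned on saline replicate 5, and stood at 0.39 and 0.41 without it. The week 1 value of miR-451a was -0.20 without saline replicate 4.

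Among the lists at week 4, the miR-17 to miR-92 clusters averaged 0.79 over 10 members, the miR-29 and miR-30 families 0.67 over 8 and the cartilage and osteoarthritis list 0.51 over 12, with no member past the threshold and 1, miR-22-3p, when adjusted over the list alone. All of these shifts were lost with an estimated correlation (adjusted p = 0.844 with an estimated correlation), and the members were higher on 5, 4 and 4 of 6 slides. Without saline replicate 5 the 3 means were 0.43, 0.33 and 0.19. The Sfmbt2 intron cluster, a large group of repeated mouse miRNA genes, averaged -0.38 over 19 members -0.24 without saline replicate 5 and 0.01 without scaling between arrays, again lost (adjusted p = 0.844 with an estimated correlation). The let-7 family averaged -0.22 at week 1 and -0.36 at week 16 over 8 members, none past the threshold also when adjusted over the list alone, each with adjusted p = 0.844 with an estimated correlation and lower on 3 and 4 of 6 slides. Leaving out single mice gave means from -0.54 to -0.041 at week 1 and from -0.59 to -0.11 at week 16.

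Averaged over the 3 times, miR-223-3p was the miRNA nearest to a difference between AIA and saline (0.62, SE 0.19, adjusted p = 0.424, higher on 6 of 6 slides), followed by miR-326-3p (0.68, SE 0.23), miR-324-3p (0.29, SE 0.11), miR-22-3p (0.53, SE 0.19) and miR-361-5p (0.46, SE 0.17), each at an adjusted p of 0.515. With normexp miR-324-3p stood at -0.018. limma gave 0 calls here, with 18 miRNAs at an unadjusted p under 0.05, 17 of them higher in AIA, 0 calls with slide as a block and 2 with array weights. The myeloid list averaged 0.29 over 6 members, with 1 passing when adjusted over the list alone, miR-223-3p (adjusted p = 0.844 with an estimated correlation). The miR-29 and miR-30 families averaged 0.27 and the Sfmbt2 cluster -0.17, both with adjusted p = 0.844 with an estimated correlation. A test of whether the AIA effect differed between the times gave 0 limma calls and 12 miRNAs at an unadjusted p under 0.05 (smallest adjusted p = 0.972), 0 with slide as a block and 5 with array weights.

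The second comparison asked the same of destabilised and sham operated knees. miR-3102-5p was higher in DMM than in sham mice at week 16, at 9.01 ± 0.64 (SD, n = 5) against 7.53 ± 0.63 (SD, n = 6) log2 units (log2 fold change 1.48, SE 0.36, adjusted p = 0.0316). It was higher on all 3 slides, and its fold change was 1.56 (SE 0.36, adjusted p = 0.0143) with slide as a block. Its probe maps to chromosome 7 from 108030830 to 108030841 (mm9). In the same comparison miR-3081-5p (0.78), miR-203-3p (1.60), miR-3473b (-1.28), miR-1982-5p (0.68), miR-3473a (-1.11), miR-205-5p (1.60), miR-669f-3p (0.70) and miR-200a-3p (0.53) had the next smallest p, with miR-3091-5p (at least 1.35-fold), all at an adjusted p of 1. With normexp miR-669f-3p stood at -0.053 and miR-200a-3p at -0.12. No miRNA passed at week 1, where miR-5128 (-1.08, SE 0.41), miR-3473e (-0.93, SE 0.42), miR-505-5p (0.22, SE 0.10) and miR-3472 (-0.89, SE 0.48) were nearest (adjusted p = 0.938). None passed at week 4 either, where the muscle miRNA miR-206-3p (-0.85, SE 0.33), miR-652-3p (0.66, SE 0.31), miR-466h-3p (0.67, SE 0.33) and miR-128-3p (0.97, SE 0.49) were nearest (adjusted p = 0.797). miR-206-3p was above background in 1 of 6 DMM and 4 of 6 sham mice. limma gave 0, 0 and 1 calls at weeks 1, 4 and 16, with 3, 3 and 6 miRNAs at an unadjusted p under 0.05, and the same counts with slide as a block, against 12, 0 and 3 with array weights. The miR-3102-5p call was lost without any 1 of 8 of the 11 mice (DMM replicates 1, 2, 4 and 5 and sham replicates 2, 3, 4 and 5; adjusted p from 0.0548 to 0.269), while its fold change stayed between 1.33 and 1.73. It was also lost without scaling (2.03, adjusted p = 0.115), with normexp background (1.12, adjusted p = 0.215) and with Agilent's total gene signal (1.27, adjusted p = 0.575). The same held in the authors' normalized table (1.15, adjusted p = 0.0533), with array position as a covariate (1.53, adjusted p = 0.101) and with these groups alone in the fit (1.48, adjusted p = 0.556). miR-451a had fold changes of 0.25, 0.59 and -0.24 and miR-23a-3p of -0.03, 0.09 and 0.26 at weeks 1, 4 and 16. Without week 4 sham replicate 6, whose miR-451a lay far below the others, the 0.59 was 0.030.

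Of the lists in DMM against sham mice, the muscle list averaged -0.59 over 5 members at week 1 (adjusted p = 0.844 with an estimated correlation, and 0.0545 with slide as a block), with miR-133a-3p at -0.93 (SE 0.55), miR-133b-3p at -0.90 (SE 0.54), miR-499-5p at -0.19 and the muscle miRNA miR-1a-3p at -0.83. At the same week the let-7 family averaged 0.46, the miR-17 to miR-92 clusters 0.40 and the GC-rich or recently numbered list -0.35, each with adjusted p = 0.844 with an estimated correlation, in that direction on 5, 5 and 4 of 6 slides. Without sham replicate 4 these means were 0.27, 0.14 and -0.16. At week 4 the miR-17 to miR-92 clusters averaged 0.59, the miR-29 and miR-30 families 0.49 and the Sfmbt2 cluster -0.35 (adjusted p = 0.844 with an estimated correlation), in that direction on 3, 2 and 3 of 3 slides. Without sham replicate 6 they were 0.16, 0.10 and -0.10. No member of these lists passed over all miRNAs or adjusted over the list alone. Averaged over the times, miR-669f-3p (at least 1.14-fold), miR-128-3p (0.68, SE 0.29), miR-130a-3p (0.67, SE 0.29) and miR-3102-5p (0.46, SE 0.20) were nearest to a difference, at an adjusted p of 0.879. limma gave 0 calls over all times (8 miRNAs at an unadjusted p under 0.05) and 0 for a difference of the DMM effect between times (4 at an unadjusted p under 0.05), both also 0 with slide as a block, and 0 and 11 with array weights. Averaged over the times the myeloid list stood at 0.33 and the muscle list at -0.32, the miR-17 to miR-92 clusters at 0.38 and the GC-rich list at -0.12, the last at 0.12 without scaling (adjusted p = 0.844 with an estimated correlation for each). With slide as a block the last 2 were lost (adjusted p = 0.0504 and 0.113).

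**Figure D1:**
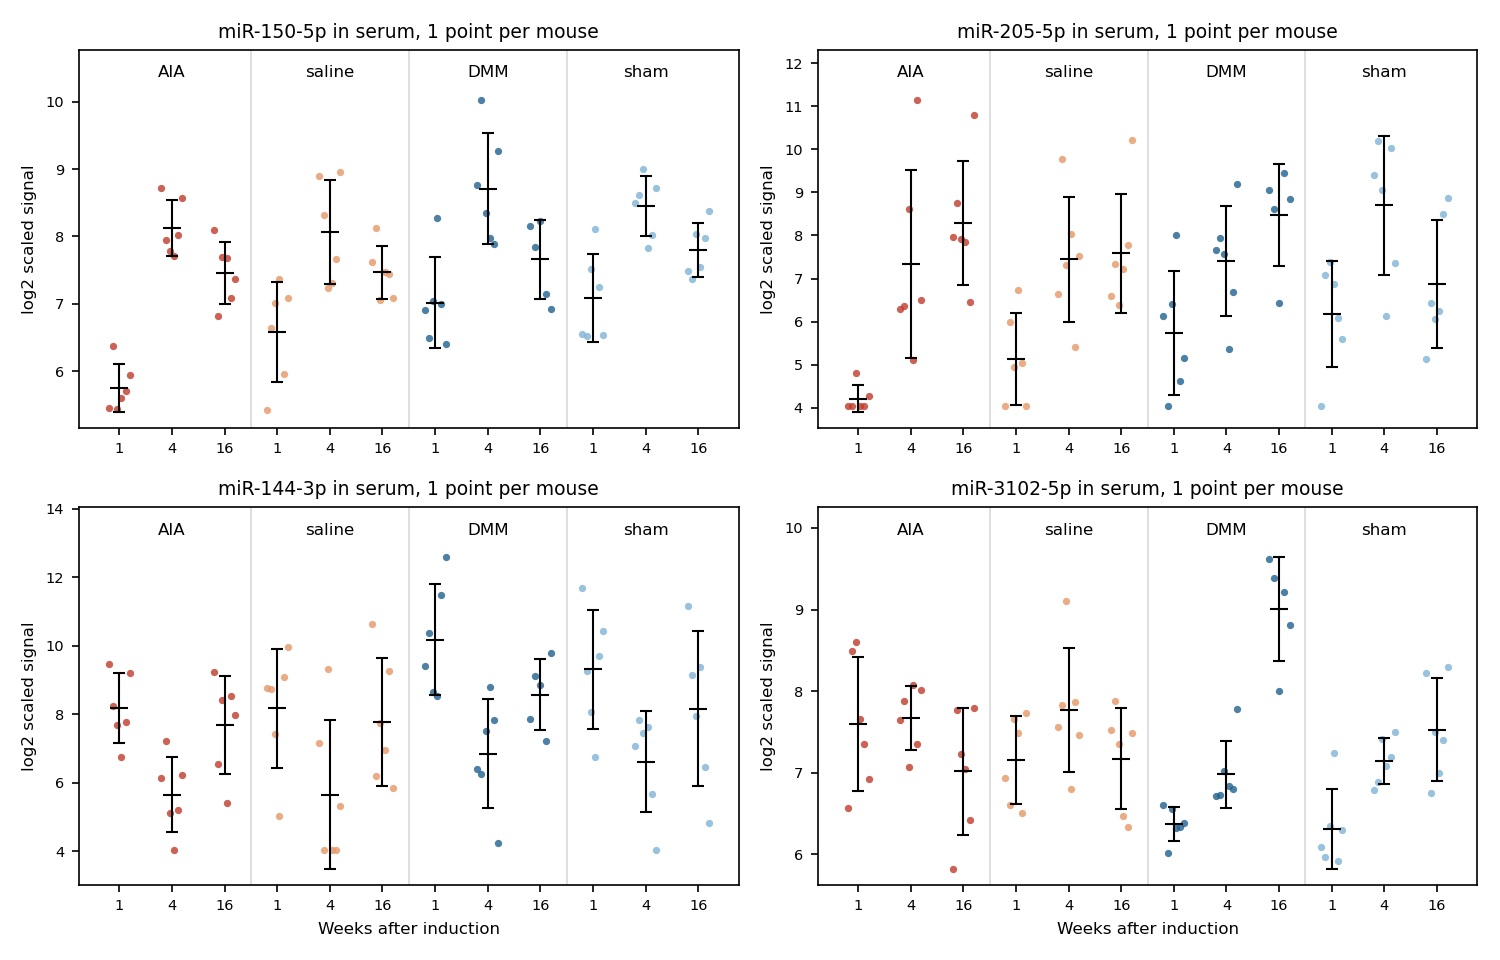
Log2 scaled signal of 4 miRNAs in each of the 71 mice by treatment and week, with points for mice and bars for the group mean and SD. In immunised mice miR-150-5p and miR-205-5p were higher at weeks 4 and 16 than at week 1 and miR-144-3p was lower at week 4, and miR-3102-5p was highest in the week 16 DMM group.

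Serum of immunised mice differed widely between weeks 1 and 4. miR-150-5p, a miRNA of mature B and T cells, rose by 1.93 log2 units (3.81-fold, SE 0.24, adjusted p = 1.25e-08), from 5.75 ± 0.36 to 8.12 ± 0.42 (SD, n = 6 each) in AIA and from 6.58 ± 0.75 to 8.06 ± 0.78 (SD, n = 6 each) in saline mice. The epithelial miRNA miR-205-5p rose most (2.71, SE 0.55, adjusted p = 0.00012), and the red cell miRNAs miR-144-5p (-2.59, SE 0.57, adjusted p = 0.000307), miR-144-3p (-2.52, SE 0.64) and miR-451a (-1.39, SE 0.31, adjusted p = 0.000419) fell. A total of 110 miRNAs passed, 55 higher and 55 lower at week 4. Each of the 20 with the largest changes moved the same way on 6 of 6 slides, and 123 passed with slide as a block. Also raised were miR-669n (2.31), miR-32-3p (2.29), miR-468-3p (2.27), miR-3082-5p (2.22), miR-1187 (2.21), miR-466i-5p (2.17), miR-574-5p (2.06) and miR-494-3p (2.04). Also lowered were the blood cell miRNA miR-142a-3p (-2.11), let-7f-5p (-2.04), miR-19a-3p (-1.74), miR-26b-5p (-1.71), miR-29b-3p (-1.69), miR-106b-5p (-1.64), miR-15a-5p (-1.62) and let-7d-5p (-1.55), all at an adjusted p of 0.00271 or less. miR-144-5p was above background in 3 of 12 mice at week 4 and 11 of 12 at week 1, and miR-205-5p in 10 and 7 of 12. The chosen probes map, on mm9, to chromosome 7 from 52377139 to 52377153 (miR-150-5p) and chromosome 1 from 195333670 to 195333684 (miR-205-5p). The red cell miRNAs lie on chromosome 11, from 77886513 to 77886534 (miR-144-5p), 77886550 to 77886568 (miR-144-3p) and 77886689 to 77886709 (miR-451a).

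Red cell miRNAs averaged -1.13 between weeks 1 and 4, and 5 of 8 members fell, miR-20b-5p (-1.51) and miR-16-5p (-1.19) besides those named (adjusted p = 0.844 with an estimated correlation, and 5 of 8 also adjusted over the list alone). The other members, miR-486a-5p, miR-92a-3p and miR-25-3p, were not among those that fell. In AIA mice their means went from 11.75 to 12.22, from 11.36 to 12.03 and from 11.25 to 11.21 log2 units. The haemolysis index, log2 miR-451a minus log2 miR-23a-3p, fell by 1.52 over the same weeks (permutation p = 0.00031, adjusted p = 0.00186), and miR-23a-3p itself stood at 0.13 (adjusted p = 0.639). With the index as a covariate 30 miRNAs passed in limma, 17 of them among the 110. Within the miR-17 to miR-92 clusters 8 of 10 members fell, with a mean of -1.09 (adjusted p = 0.844 with an estimated correlation, and 8 adjusted over the list alone), among them miR-20a-5p (-1.54). In the Sfmbt2 cluster 13 of 19 members rose and 2 fell, with a mean of 0.86 (adjusted p = 0.844 with an estimated correlation, and the same 13 and 2 counts adjusted over the list alone), miR-669l-5p (at least 3.08-fold) and miR-669e-5p (at least 3.24-fold) among the risers. These 2 were above background in 11 and 12 of 12 mice at week 4 and in 2 and 3 of 12 at week 1, none of them AIA. Members of the Sfmbt2 list are repeated genes picked by name, so its 13 is not a count of independent changes. Of the cartilage and osteoarthritis list 7 of 12 fell, such as miR-140-5p of chondrocytes (-1.13), miR-483-5p (-0.72) and miR-22-3p (-0.74), and 1 rose, the inflammation-induced miR-146a-5p (0.82), with a mean of -0.61 (adjusted p = 0.844 with an estimated correlation, and 1 and 8 adjusted over the list alone). These shifts had the same direction on 6 of 6 slides. Among lists without a call, lymphocyte miRNAs were split, with 3 rising, miR-150-5p, miR-342-3p (1.40) and miR-181b-5p (0.53), and 2 falling, miR-29c-3p (-1.11) among them. In the myeloid list 4 of 6 fell, and 6 of 8 in the let-7 family. Of the 8 tested inflammation-induced miRNAs 4 rose, miR-125b-5p (1.62) and miR-125a-5p (1.21) among them, and 1 fell, miR-21a-5p (-1.16). No member of the platelet, liver or muscle list passed. The 55 to 55 split became 35 to 91 with the percentile taken over all probes, 32 to 63 without scaling, 52 to 32 with normexp and 73 to 41 with total gene signal. There the median of all miRNAs shifted by -0.33, -0.31, 0.29 and 0.21, and 9 of the 110 changed sign with normexp.

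miR-205-5p was also the most raised miRNA of immunised mice at week 16 against week 1 (3.26, SE 0.55, adjusted p = 9.35e-06), and miR-150-5p stayed above its week 1 level (1.30, SE 0.24, adjusted p = 5.02e-05). In all, 96 miRNAs passed, 51 higher and 45 lower at week 16. The gut and liver miRNAs miR-215-5p (2.03) and miR-122-5p (1.74), the epithelial miR-203-3p (at least 3.40-fold) and miR-200b-3p (at least 2.68-fold), the pancreatic islet miRNA miR-375-3p (1.80), miR-125b-5p (1.65), miR-468-3p (1.65), miR-669n (1.63) and miR-32-3p (1.58) rose at adjusted p values of 0.0297 or less. miR-721 (-2.16, SE 0.29, adjusted p = 9.82e-08), miR-1897-5p (-1.72), miR-1955-3p (-1.72), miR-3473e (-1.59), miR-3960 (-1.49), miR-1895 (-1.39), miR-208a-5p (-1.38), miR-5128 (-1.30), miR-6538 (-1.29) and miR-3091-5p (-1.29) fell, each on 6 of 6 slides. miR-375-3p was above background in 12 of 12 mice at week 16 and 4 of 12 at week 1, miR-200b-3p in 11 and 2 of 12 and miR-203-3p in 10 and 5 of 12, the last 2 in no AIA mouse of week 1. miR-451a stood at -0.23 (adjusted p = 0.638), miR-23a-3p rose by 0.63 (adjusted p = 0.0194), and the haemolysis index fell by 0.86 (permutation p = 0.0116, adjusted p = 0.0349). With the index as a covariate 106 miRNAs passed in limma, 75 of them among the 96. With slide as a block 105 miRNAs passed. The probes of miR-215-5p and miR-122-5p map on mm9 to chromosome 1 from 187137493 to 187137509 and chromosome 18 from 65408523 to 65408541.

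Of the 8 inflammation-induced miRNAs 4 rose at week 16 against week 1, miR-146a-5p, a brake on innate immune signalling (1.53, SE 0.27, adjusted p = 1.43e-05), miR-125b-5p, miR-203-3p and miR-125a-5p (0.98), and the list averaged 0.87, higher on 6 of 6 slides (adjusted p = 0.844 with an estimated correlation, and 5 members adjusted over the list alone). In the GC-rich or recently numbered list 16 of 33 fell and 3 rose, with a mean of -0.47 on 5 of 6 slides (adjusted p = 0.844 with an estimated correlation, and 19 and 3 adjusted over the list alone). In the lymphocyte list, which was not called, 4 of 7 rose, miR-342-3p (1.29) and miR-181a-5p (0.50) besides miR-150-5p and miR-181b-5p (0.39), and in the endothelial list 2 of 6, miR-10b-5p (1.02) and miR-126a-3p (1.32). Normexp left 45 calls, 17 higher and 28 lower, and the split was 42 to 61 with the percentile over all probes and 69 to 18 without scaling, where the median of all miRNAs shifted by -0.17, -0.13 and 0.35. Of the 96, 4 changed sign with normexp, miR-181a-5p (-0.038) and miR-181b-5p (-0.10) among them.

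Between weeks 4 and 16 of immunised mice the red cell miRNA miR-144-3p rose by 2.07 (SE 0.64, adjusted p = 0.00937), the muscle miRNA miR-1a-3p by 1.78 (SE 0.65), miR-26b-5p by 1.70, miR-142a-3p by 1.65, miR-144-5p by 1.61, let-7f-5p by 1.58, miR-19a-3p by 1.39, miR-15a-5p by 1.38, let-7d-5p by 1.37, miR-106b-5p by 1.31 and miR-451a by 1.16. miR-680 (-1.53, SE 0.36, adjusted p = 0.00467), miR-1897-5p (-1.42), miR-2861 (-1.38), miR-149-3p (-1.37), miR-877-5p (-1.36), miR-3960 (-1.33), miR-5126 (-1.31), miR-6538 (-1.22), miR-5131 (-1.21) and miR-1196-5p_v19.0 (-1.18) fell. A total of 125 miRNAs passed, 59 higher and 66 lower, and 136 with slide as a block. All arrays of week 4 enter this comparison and the one with week 1, so opposite signs in the 2 are partly built in. The array signal itself rose between these weeks, by 0.88 log2 units in the scaling percentile (permutation p = 0.00923, adjusted p = 0.038), and with that percentile as a covariate none of the 125 passed in limma (smallest adjusted p = 0.12, and 61 of the 280 miRNAs at an unadjusted p under 0.05). With the percentile and slide both in the fit 28 passed, 25 of them among the 125. The haemolysis index stood 0.66 higher at week 16 (permutation p = 0.0448, adjusted p = 0.0897). With the index as a covariate 79 miRNAs passed in limma, 71 of them among the 125, and the median size of the 125 fold changes went from 0.92 to 0.68. There miR-144-3p stood at 1.14 (SE 0.46, adjusted p = 0.0512). miR-451a is part of the index, so its value in that fit is not given. Both covariates were chosen after the values were seen.

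Counts by list between weeks 4 and 16 were 6 of 8 risen for red cells (mean 0.95), 8 of 10 for the miR-17 to miR-92 clusters (0.92), 6 of 8 for let-7 (0.96), 7 of 8 for the miR-29 and miR-30 families (0.74), 8 of 12 for cartilage and osteoarthritis (0.70) and 3 of 6 for the myeloid list (0.83), with no member falling. Each of these calls had adjusted p = 0.844 with an estimated correlation, and 6, 9, 7, 7, 9 and 5 members passed adjusted over the list alone. let-7g-5p (1.11), miR-20a-5p (1.20), miR-30c-5p (0.80) and miR-26a-5p (1.31) were among the members that rose. In the GC-rich list 22 of 33 fell, with a mean of -0.82 that became 0.03 without scaling (adjusted p = 0.844 with an estimated correlation, and 26 adjusted over the list alone). The directions held on 6 of 6 slides, except let-7 and the GC-rich list on 5. miR-150-5p fell by 0.63 (SE 0.24, adjusted p = 0.0316), but stood at 0.25 without scaling. The split of 59 to 66 became 68 to 37 with the percentile over all probes, 121 to 0 without scaling and 27 to 110 with normexp. The median of all miRNAs shifted by 0.19, 0.61 and -0.49, and 24 of the 125 changed sign without scaling and 14 with normexp.

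In operated mice miR-3102-5p (1.21, SE 0.25, adjusted p = 0.00228) and miR-362-3p (0.82, SE 0.22, adjusted p = 0.0295) rose and miR-706 (-0.98, SE 0.26, adjusted p = 0.0295) fell between weeks 4 and 16, each the same way on 3 of 3 slides. The mean of miR-3102-5p went from 6.98 to 9.01 log2 units in DMM and from 7.15 to 7.53 in sham mice, and the test of the DMM effect between times gave it an adjusted p of 0.871. The separate entry miR-3102-5p.2-5p did not rise with it, with means of 6.34 at week 4 and 6.26 at week 16 in DMM mice. miR-706 was above background in 5 of 11 mice at week 16 and 9 of 12 at week 4. miR-362-3p was so in 6 of 11 and 2 of 12 mice, and stood at -0.22 with normexp, where miR-101c stood at -0.16, and miR-296-5p stood at 0.047 without scaling. miR-150-5p (-0.85, SE 0.25), miR-296-5p (-0.75), miR-3473a (-1.30), miR-466h-3p (at least 1.53-fold lower) and miR-877-3p (-0.88) followed at an adjusted p of 0.0573, as did miR-101c (at least 1.06-fold higher), and then miR-3473b (-1.27, adjusted p = 0.075). limma called 3 miRNAs, with 57 at an unadjusted p under 0.05, and 9 with slide as a block. Normexp and total gene signal left 0 calls and no scaling gave 23. The scaling percentile rose in operated mice too, by 0.77 log2 units (permutation p = 0.0127, adjusted p = 0.038). With it as a covariate miR-3102-5p alone passed (1.33, SE 0.25, adjusted p = 0.000478). The calls of miR-706 (-0.92, adjusted p = 0.162) and miR-362-3p (0.55, adjusted p = 0.373) were lost, and 27 miRNAs stayed at an unadjusted p under 0.05. The myeloid list averaged 0.62 and the miR-17 to miR-92 clusters 0.48, each higher on 3 of 3 slides, and the GC-rich list -0.31, but 0.48 without scaling and 0.01 with the scaling percentile as a covariate, each with adjusted p = 0.844 with an estimated correlation. Adjusted over the list alone, no myeloid or miR-17 to miR-92 member passed, and in the GC-rich list 4 fell and 1 rose, miR-3102-5p. miR-451a stood at 0.40 and miR-23a-3p at 0.21, and at 0.12 and 0.11 without week 4 sham replicate 6, where the miR-17 to miR-92 mean was 0.26. When the 2 weekly changes were compared, that of miR-3102-5p was lower in immunised than in operated mice (difference -1.83, SE 0.35, adjusted p = 0.000458), the only miRNA to pass, with 22 at an unadjusted p under 0.05. This test was chosen after the values were seen. At weeks 4 and 16 the 2 models lay on different slides, and all operated arrays shared 1 of 2 scan days. An effect of slide or scan day on the change was not separated from the model.

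At week 1 the serum of AIA and DMM mice differed in 95 miRNAs, 65 higher and 30 lower in AIA. GC-rich and recently numbered miRNAs such as miR-1895 (2.19, SE 0.38, adjusted p = 2.68e-05), miR-709 (2.12), miR-721 (1.94), miR-1892 (1.89), miR-3960 (1.86) and miR-149-3p (1.79) were higher in AIA. So were miR-3472 (2.49, SE 0.48, adjusted p = 0.000159), miR-370-3p (1.82), miR-1897-5p (1.79) and miR-1955-3p (1.78). Lower in AIA were let-7f-5p (-1.92), let-7d-5p (-1.89), let-7a-5p (-1.88, SE 0.51, adjusted p = 0.0038), miR-98-5p (-1.58) and let-7c-5p (-1.42, SE 0.32, adjusted p = 0.000992) of the let-7 family of differentiated cells. So were miR-144-5p (-2.18), miR-374c-5p (-1.83), miR-103-3p (-1.79), miR-194-5p (-1.46) and miR-15b-5p (-1.28). miR-150-5p was lower in AIA as well (-1.27, SE 0.35, adjusted p = 0.0038, on 6 of 6 slides). The smallest p was that of miR-483-5p (1.68, SE 0.29, adjusted p = 2.68e-05), higher on 6 of 6 slides, whose probe lies on chromosome 7 from 149840846 to 149840857 (mm9). AIA and DMM mice differ in immunisation, in surgery and in the joint lesion. The labels also give AIA mice a younger age at the first procedure than DMM mice, and place the knee injection after the immunisations.

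Let-7 family members were lower together in AIA than in DMM mice, with 7 of 8 past the threshold and a mean of -1.50 on 6 of 6 slides (adjusted p = 0.844 with an estimated correlation, and 8 adjusted over the list alone). Of the red cell list 3 of 8 were lower, miR-486a-5p (-1.12), miR-25-3p (-1.09) and miR-144-5p, with a mean of -1.10 on 6 of 6 slides (adjusted p = 0.844 with an estimated correlation, and 3 adjusted over the list alone). miR-451a stood at -0.55 (adjusted p = 0.388), miR-23a-3p at 0.29, and the haemolysis index 0.84 lower in AIA, a difference of -0.84 (exact permutation p = 0.0606, adjusted p = 0.0909). With the index as a covariate 65 miRNAs passed in limma, 63 of them among the 95. In the GC-rich list 23 of 33 were higher and 1 lower, with a mean of 1.12 on 5 of 6 slides (adjusted p = 0.844 with an estimated correlation, and 23 and 1 adjusted over the list alone). Of the bone and fibroblast list 2 of 8 were higher, miR-2861 (1.71) and miR-3960, and of the brain and nerve list 1 of 4 was lower, miR-7a-5p (-0.77). With slide as a block 109 miRNAs passed. Without scaling 28 passed and with normexp 51, and 68.4% were higher in AIA with the main scaling. That share was 43.8% with the percentile over all probes, 57.5% with quantile normalization, 14.3% without scaling and 45.7% in the authors' table. The median of all miRNAs shifted from 0.12 to -0.21, -0.27 and 0.40 with the percentile over all probes, without scaling and with normexp, and 5 of the 95 changed sign with normexp, miR-7a-5p (0.020) among them.

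**Figure D2:**
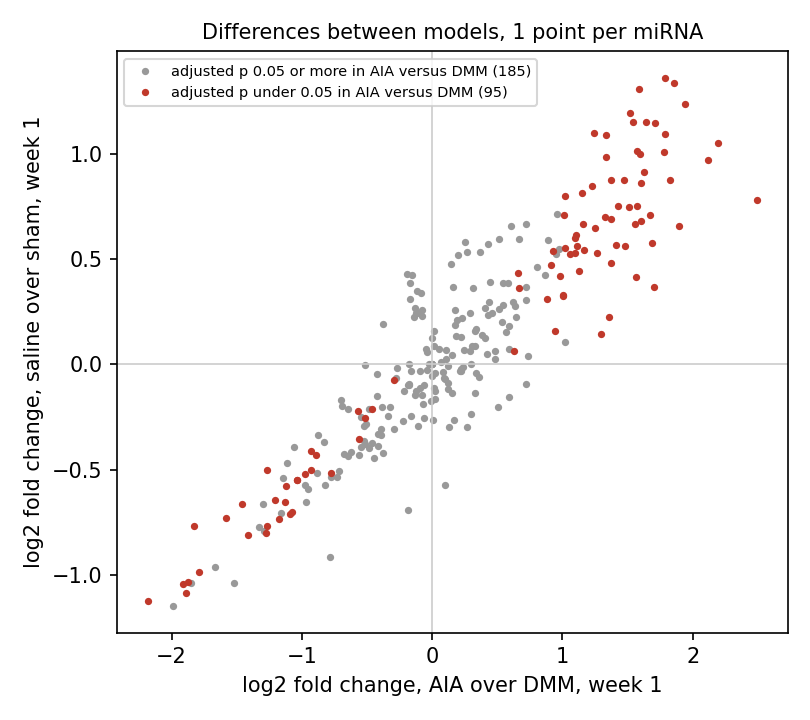
Log2 fold change of saline over sham mice against that of AIA over DMM mice at week 1, with 1 point for each of the 280 tested miRNAs and red for the 95 that passed in AIA against DMM. The 2 axes share no mice and correlated at a Pearson r of 0.918 across miRNAs.

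The control mice of the 2 models, saline and sham, were compared at the same week. miR-3091-5p (1.31, SE 0.40), miR-721 (1.23, SE 0.41), miR-1901 (0.87, SE 0.30) and miR-331-3p (-0.77, SE 0.27) were nearest to a difference, at an adjusted p of 0.31. limma gave 0 calls, with 34 miRNAs at an unadjusted p under 0.05, 0 calls with slide as a block and 46 with array weights. Without week 1 saline replicate 2, miR-3091-5p passed (adjusted p = 0.0496). All 95 miRNAs that passed between AIA and DMM had the same sign between saline and sham, with a median ratio of the fold changes of 0.516. The GC-rich list averaged 0.60 and was higher on 6 of 6 slides, and the let-7 family averaged -0.82, the red cell list -0.65 and the miR-17 to miR-92 clusters -0.38, lower on 5, 6 and 6 of 6 slides, with no member past the threshold also when adjusted over the list alone (adjusted p = 0.844 with an estimated correlation for each). A test of whether the AIA effect differed from the DMM effect at week 1 gave 0 limma calls and 7 miRNAs at an unadjusted p under 0.05, led by miR-483-5p (1.11, SE 0.41, adjusted p = 0.982), with 0 calls with slide as a block and 66 with array weights. In that difference the let-7 family averaged -0.68 and the GC-rich list 0.52 (adjusted p = 0.844 with an estimated correlation for each), in that direction on 4 and 5 of 6 slides, and no member passed adjusted over the list alone.

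The haemolysis index showed no detected difference between either model and its controls. Its group means lay between 3.35 ± 0.87 (SD, n = 6) in week 4 saline mice and 5.70 ± 0.74 (SD, n = 6) in week 1 DMM mice, and the treated and control groups differed by -0.50 to 0.50 (two-sided exact permutation tests, smallest p = 0.325, smallest adjusted p = 0.737). The highest of these, DMM against sham at week 4, was 0.13 without sham replicate 6, and the lowest, at week 16, was -0.24 without DMM replicate 4. When arrays were permuted within slides the smallest exact p was 0.125. The number of detected miRNAs did not pass in any of the 6 comparisons with controls either, the largest difference being 39.3 more miRNAs in DMM than in sham mice at week 16 (exact p = 0.173, adjusted p = 0.926).

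**Figure D3:**
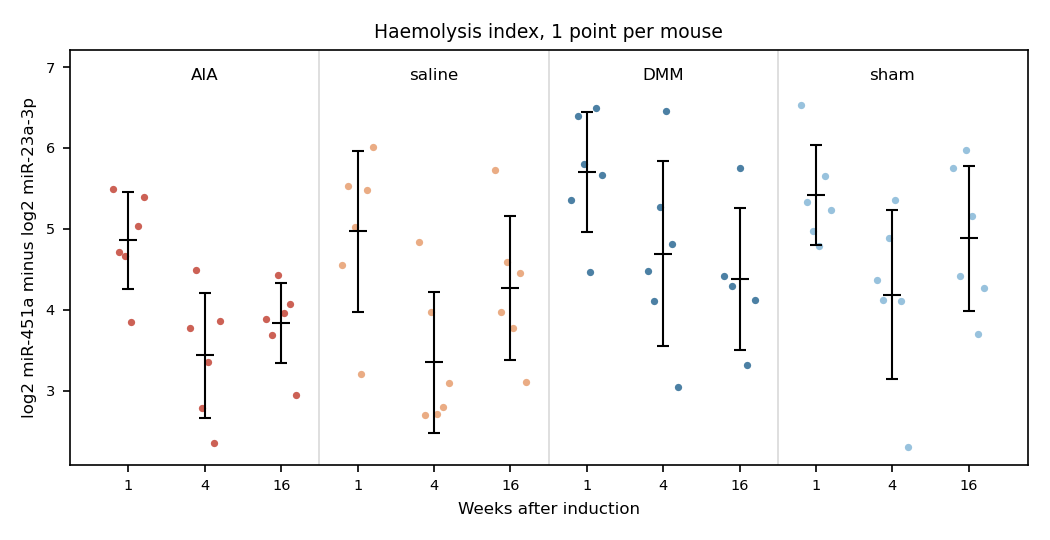
Haemolysis index, log2 miR-451a minus log2 miR-23a-3p, in each of the 71 mice by treatment and week, with points for mice and bars for the group mean and SD. The index of immunised mice was lower at weeks 4 and 16 than at week 1, and treated and control groups overlapped at each week.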

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

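The tests with array signal as a covariate, the tests of miR-150-5p, of weeks 4 to 16 and of the models with the haemolysis index and the comparison of weekly changes between models were chosen after the result was seen, as was the present reading of 2 correlation tests against shuffled arrays.

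The change of miR-3102-5p from week 4 to week 16 differed between immunised and operated mice by -1.83 log2 units (limma SE 0.35, adjusted p = 0.000458), and no other miRNA passed that test, with 22 at an unadjusted p under 0.05. Immunised and operated mice lay on different slides at these weeks, so slide was not separated from the model. The largest of the 4 changes was that of DMM mice: means went from 6.98 to 9.01 in DMM, from 7.15 to 7.53 in sham, from 7.67 to 7.02 in AIA and from 7.77 to 7.17 in saline mice. At week 1 the mean difference of the AIA and DMM effects was -0.68 over the let-7 family and 0.52 over the GC-rich list, each past the preset list test and each with adjusted p = 0.844 with an estimated correlation.

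In 13 of 132 groups tested over 11 measures, 1 mouse lay far from the others of its group, where about 1 in 20 groups does so by chance. Epithelial miR-205-5p stood at 10.20 log2 units in week 16 saline replicate 6, against 6.38 to 7.79 in the others, and at 6.44 in week 16 DMM replicate 3 (others 8.61 to 9.45). It stood at 4.81 in week 1 AIA replicate 3 (others 4.05 to 4.28). There 4.05 is the floor and the miRNA was above background in 2 of 6 mice, so that flag says little. Red cell miR-451a stood at 12.73 in week 4 sham replicate 6 (others 15.88 to 16.33) and at 14.69 in week 1 saline replicate 4 (others 16.05 to 16.81). Lymphocyte miR-150-5p stood at 8.27 in week 1 DMM replicate 4 (others up to 7.04). miR-3102-5p stood at 7.24 in week 1 sham replicate 4 (others 5.92 to 6.34) and at 7.79 in week 4 DMM replicate 6 (others 6.71 to 7.02). The log2 scaling percentile was low in week 1 saline replicate 4 (9.24, others 11.11 to 11.96), week 1 sham replicate 4 (9.02, others 11.36 to 12.32), week 4 AIA replicate 4 (9.88, others 10.85 to 11.27) and week 16 saline replicate 2 (10.32, others 11.35 to 11.85). Week 4 DMM replicate 3 had 165 detected miRNAs, against 221 to 245 in the others.

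Between weeks 4 and 16 of immunised mice 125 miRNAs changed while array signal rose. With the scaling percentile as a covariate 0 of the 125 passed in limma, with 61 of 280 miRNAs at an unadjusted p under 0.05, because fold changes shrank. Their median size went from 0.92 to 0.47 while the median SE went from 0.30 to 0.26, miR-144-3p from 2.07 (SE 0.64) to 0.97 (SE 0.55), and with the percentile and slide 28 passed, 25 of them among the 125. The slope of a miRNA on the percentile within groups correlated with its fold change across miRNAs, which are not independent and whose slope and fold carry the same scaling, at 0.875, but 6 of 100 sets of shuffled weeks gave as high a value (highest 0.934), so by the criterion set beforehand it did not exceed them; that criterion was a poor one, since shuffled arrays differ along the same signal axis, and this was seen only after the result. Array signal may account for much of this difference, red cell RNA stays open for part of it, with 79 calls left with the haemolysis index as a covariate, and a change of serum miRNA with time stays open, since the test of one shared by both models did not separate it from array signal.

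Between weeks 1 and 4 of immunised mice 110 miRNAs changed. With the scaling percentile as a covariate 111 passed, 96 of them the same, which argues against array signal as the whole source. With the haemolysis index as a covariate 30 passed, 17 of them among the 110. The median size of the 110 fold changes went from 1.11 to 0.55 with the SE at 0.31 in both. miR-144-3p went from -2.52 to -0.37, but it lies beside miR-451a of the index, so its smaller change is partly built in. The epithelial miR-205-5p also went from 2.71 to 1.14, so the index may follow more than red cell RNA. Red cell RNA may account for part of the difference and cannot be told apart from the weeks, between which the index itself differs. Of the red cell list, miR-486a-5p, miR-92a-3p and miR-25-3p were not among the miRNAs that fell. The rise of miR-150-5p stayed at 1.77 (limma SE 0.28, adjusted p = 5.87e-06) with the haemolysis index as a covariate, which argues against red cell RNA as its source. Age and time since immunisation stay open for it and were not tested.

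At week 1, 95 miRNAs differed between AIA and DMM mice. With the scaling percentile as a covariate 83 passed, 74 of them the same, which argues against array signal as the whole source, and with the haemolysis index 65 passed, 63 of them the same and their median size from 1.29 to 1.06, so red cell RNA stays open for part. Saline and sham mice, which share no mice with the others, gave fold changes correlated with those of AIA and DMM at 0.918 across miRNAs (Spearman rho 0.903), above each of 100 shuffles of these arrays (highest 0.881). Shuffled arrays also differ in signal, which makes their correlations high, so this criterion is weak here too. With the scaling percentile as a covariate r was 0.893. A difference between the models that their controls share, such as immunisation with adjuvant, surgery or housing, may underlie much of the difference between AIA and DMM mice. Which of these does was not tested, since the design varies them together.

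Other splits of the same mice, 100 with the real one included, tested how often a split gave as high a count. Under 5 of 100 splits, the criterion set beforehand, gave as many calls for week 4 against week 1 (1 of 100 splits, 110 against 96 in the highest other), week 16 against week 1 (1 of 100, 96 against 27), week 16 against week 4 in immunised mice (2 of 100, 125 against 150) and AIA against DMM at week 1 (2 of 100, 95 against 98). Chance is less likely for these counts but is not excluded. Another split gave more calls than the real one where the highest other was 150 or 98. The criterion was not met for DMM against sham at week 16 (16 of 100 splits gave at least 1 call, highest other 15) or week 16 against week 4 in operated mice (5 of 100, 3 against 29), so chance was not excluded there either. These splits moved mice across slides in the fit without a block; with slide as a fixed or random block operated mice gave 9 and 10 calls, and no splits were run in those fits. For the comparisons without a call the miRNAs at an unadjusted p under 0.05 were counted, and chance was excluded for none of them: AIA against saline at weeks 1, 4 and 16 (50, 15 and 90 of 100 splits, with 5, 41 and 1 miRNAs against 78, 85 and 91 in the highest other), DMM against sham at weeks 1 and 4 (32 and 92 of 100, 3 and 3 against 82 and 71), AIA and DMM over all weeks (22 and 39 of 100, 18 and 8 against 119 and 82), the AIA and DMM effects by week (33 and 67 of 100, 12 and 4 against 80 and 64), the difference of the effects at week 1 (32 of 100, 7 against 71) and saline against sham (12 of 100, 34 against 110). Splits of comparisons without a call reached 76 calls for AIA over all weeks and 52 for saline against sham, which points to a structure among the arrays. After each miRNA was centred, arrays of different groups correlated at a median of 0.156 on the same slide and -0.0097 on different slides. Whole arrays correlated at 0.377 or more. Whether slide led to the counts from splits was not tested. Splits that kept slides whole and gave as many numbered 1, 1 and 2 for AIA against saline at weeks 1, 4 and 16, and with slide as a block these comparisons gave 0, 2 and 0 calls.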

How the results depend on the processing

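The covariates for array signal and the haemolysis index and the removal of 4 arrays with low signal were chosen after the data were seen. So were the list means and the values of miR-451a, miR-23a-3p and the index without single mice. The other alternatives were chosen before. The cause was not tested for any change below, except where fewer miRNAs or mice entered the test.

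With quantile normalization and with the replicate number as a block, each of the 17 limma counts stayed within 1.5 times its value. The replicate block gave 113, 104 and 132 calls for week 4 against 1, week 16 against 1 and week 16 against 4 in immunised mice, 98 for AIA against DMM, 3 for operated mice, 1 for DMM against sham at week 16 and 0 elsewhere; the labels do not pair the mice, and correlations of same-numbered mice ran from -0.64 to 0.82. Of 35 such pairs 33 lay on 1 slide, so this block is largely a slide block. Arrays of different groups had a median correlation of 0.156 on the same slide and -0.0097 on different slides. These correlations and those of same-numbered mice were taken after each miRNA was centred, and whole arrays correlated at 0.377 or more.

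Array weights, whose estimation did not converge, gave 68, 1 and 1 calls for AIA against saline at weeks 1, 4 and 16, 12 and 3 for DMM against sham at weeks 1 and 16, 2 for AIA over all weeks, 5 and 11 for the AIA and DMM effects by week, 66 for the difference of the effects, 172 for AIA against DMM, 46 for saline against sham and 62 for week 16 against 4 in operated mice.

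AIA against saline at week 4 went from 0 to 2 calls with a higher floor, 1 with miRNAs detected on at least 1 array, 1 with total gene signal and 2 with slide as a fixed or a random block. The single call of DMM against sham at week 16 became 0 with no scaling, normexp, total gene signal, the authors' table, array position and these groups alone. With miRNAs detected on all 71 arrays, where 72 were tested, 23, 33 and 46 passed for week 4 against 1, week 16 against 1 and week 16 against 4 in immunised mice, 41 for AIA against DMM and 5 in operated mice. With normexp 45 passed for week 16 against 1 and 51 for AIA against DMM, and without scaling 28 for the latter. With the signal covariate 0 passed for week 16 against 4 in immunised mice, and 28 with slide in that fit too. The 3 calls of operated mice became 1 with the percentile over all probes, array position, these groups alone, the signal covariate or without low-signal arrays, 0 with normexp or total gene signal, 5 with the mean of all probes or without a trend, 6 with miRNAs detected on at least 1 array or the authors' table, 8 with a lower floor, 9 and 10 with slide as a fixed and random block and 23 without scaling. The 45 list calls became 0 with an estimated correlation. In the 6 comparisons of treated with control mice, the haemolysis index and detected miRNAs gave 0 calls in each alternative.

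Leaving out each mouse in turn gave 0 to 1, 0 to 10 and 0 to 0 calls for AIA against saline at weeks 1, 4 and 16, 0 to 0, 0 to 0 and 0 to 1 for DMM against sham, 66 to 103 for AIA against DMM and 0 to 1 for saline against sham. Calls between weeks, over all weeks and for the differences of effects had no such removals. The 1 call at week 1 came without saline replicate 1 and that of saline against sham without saline replicate 2. At week 4, 1, 2 and 10 came without saline replicates 3, 4 and 6. Without saline replicate 5 the smallest adjusted p in limma at that week went from 0.0913 to 0.67. Without DMM replicate 1 miR-3102-5p had a fold change of 1.33 (adjusted p = 0.269), and over all its alternatives and removals adjusted p ranged from 0.00571 to 0.575.

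Among the named miRNAs, these changed sign. With normexp, miR-324-3p stood at -0.28 (AIA, week 4) and -0.018 (AIA, all weeks), miR-669f-3p at -0.053 and miR-200a-3p at -0.12 (DMM, week 16), miR-362-3p at -0.22 and miR-101c at -0.16 (operated, week 16 against 4), miR-181a-5p at -0.038 and miR-181b-5p at -0.10 (week 16 against 1) and miR-7a-5p at 0.020 (AIA against DMM). Without scaling, miR-296-5p stood at 0.047 (operated) and miR-150-5p at 0.25 (week 16 against 4). miR-451a and miR-23a-3p, with fold changes near 0, moved across it more often. miR-451a stood at 0.27, 0.30 and 0.12 with quantile normalization, no scaling and the authors' table in DMM at week 16, at -0.016, -0.15, -0.12 and -0.20 with the percentile over all probes, no scaling, array weights and without low-signal arrays in AIA at week 1, at 0.14 with quantile normalization in AIA at week 16, at -0.068 in the authors' table in DMM at week 1 and at 0.16 without scaling for week 16 against 1. miR-23a-3p stood at -0.036 without scaling in AIA at week 1, at 0.11 and 0.041 with the percentile over all probes and no scaling in DMM at week 1, at -0.022, -0.11 and -0.10 with quantile normalization, the authors' table and without low-signal arrays in DMM at week 4, at -0.22 and -0.29 with the percentile over all probes and no scaling in AIA against DMM and at -0.32 and -0.36 with the same 2 for week 4 against 1. Of the 45 called list means 23 moved by more than 1.5 times without a single mouse, none of them past 0. For AIA against saline these were saline replicate 5 and AIA replicate 2 at week 4, AIA replicates 1, 2 and 4 and saline replicates 2, 4, 5 and 6 at week 1, and AIA replicates 1 and 4 and saline replicates 1, 5 and 6 at week 16. For DMM against sham they were DMM replicates 5 and 6 and sham replicates 1 and 4 at week 1 and DMM replicate 1 and sham replicate 6 at week 4. Over all weeks they were week 4 saline replicate 5, week 1 saline replicate 4, week 4 sham replicates 1 and 6, week 16 DMM replicate 3, week 1 sham replicate 4 and week 16 sham replicate 6. For saline against sham they were sham replicates 1 and 4 and saline replicate 4, for the difference of effects week 1 sham replicate 4 and for operated mice week 4 sham replicate 6. Without sham replicate 6 miR-451a went from 0.59 to 0.030 in DMM at week 4, and without saline replicate 5 miR-451a and miR-23a-3p went from 0.83 and 0.74 to 0.39 and 0.41 in AIA at week 4. Signal over background limits how well dim miRNAs are measured (miR-324-3p was detected in 1 of 6 saline mice at week 4), and whether it led to any sign change was not tested.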

Other observations

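The test of a change with time shared by both models was written beforehand, and its present reading, the contrast of all immunised with all operated mice and the slopes on array signal were chosen after the data were seen.

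With all AIA and saline mice against all DMM and sham mice at week 1, 107 miRNAs passed in limma, 67 higher and 40 lower in immunised mice. miR-150-5p of lymphocytes was lower in immunised mice (-0.89, SE 0.24, adjusted p = 0.0032), as was miR-126a-3p of endothelium and platelets (-0.85, SE 0.35, adjusted p = 0.0499), and the neutrophil miRNA miR-223-3p stood at 0.44 (SE 0.23, adjusted p = 0.135). miR-3102-5p was higher in immunised mice at week 1 (1.04, SE 0.24, adjusted p = 0.000795).

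Signals before scaling rose less with array signal for some lists than for others. Within groups, the median slope of log2 unscaled signal on the log2 scaling percentile was 0.54 over the 33 GC-rich or recently numbered miRNAs and 0.24 over the 19 miRNAs of the Sfmbt2 cluster, against 1.49 in the let-7 family, 1.55 in the miR-17 to miR-92 clusters and 0.62 over all 280. Slopes were computed for 16 lists and each miRNA and were not tested. Values set to the floor cannot rise with array signal, so dim miRNAs have slopes held near 0. Several Sfmbt2 members are dim, such as miR-466j, above background in 0 of 6 AIA mice at week 1. The low slope of that list may thus reflect the floor. For miRNAs above the floor on all arrays, division by the percentile turns a slope under 1 negative. With floored values it need not, as in the lymphocyte list (median 0.77 before and 0.16 after scaling). The scaled median slope of -0.44 in the GC-rich list therefore does not show that its signal fell.

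A change with time shared by both models was tested as a hypothesis, by correlating the fold changes of week 16 against week 4 in operated mice with those in immunised mice across miRNAs. The Pearson r was 0.646, with 114 of the 125 miRNAs called in immunised mice of the same sign in operated mice, but 16 of 100 shuffles of the operated arrays' weeks gave as high a value (highest 0.847). By the criterion set beforehand the correlation did not exceed shuffled weeks. Shuffled arrays also differ in signal, which makes their correlations high, so that criterion could not separate the 2 cases, a point seen only after the result. With the scaling percentile as a covariate r was 0.05. That percentile is taken from miRNA probes of the same arrays and rose in both models. The fit would thus also remove a shared rise of serum miRNA, and it cannot separate the 2 cases either.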
